A study of Mus musculus with 6 samples.

How the data were processed

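The samples were parietal bones of 10-day-old mice, embedded, cryosectioned and extracted with TRIZOL, and their RNA was amplified to biotin-labelled antisense RNA, per the labels' protocols. The deposited values are intensities on a linear scale, 1 per probe set and sample, and the submitters' processing notes name MAS5, with its version not given in the sources used here. The trimmed mean of the deposited intensities, leaving out 2% at each end, was 500.003 on each array, so the arrays had been brought to one level before deposit. MAS5 takes background from each array and gives no values below 0, and low signals from it are noisy on a log scale, which is why a pseudocount and a filter were used. No detection calls, scan dates or batches were used here. The labels give 2 genotypes with 3 biological replicates each, and wild type is called control here.

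The deposited columns of control 1 and 13del-tg 1 were identical for 45101 of 45101 probe sets. The design fixed before the data were examined set all 6 columns against each other, 3 against 3. Because 1 array cannot have both genotypes, it was left out before any model was fitted, and the comparison reported is 2 controls (2 and 3) against 2 13del-tg (2 and 3). The 3 against 3 fit as first designed, and fits with the shared array as control only or as 13del-tg only, were added as alternatives after the data were seen. The shared array's genotype was not inferred from its values.

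Intensities were transformed as log2(signal + 16) and used with no further normalization. The 64 control probe sets were left out of the test. Probe sets with a mean log2 value over the 5 distinct arrays at or above the 40th percentile (6.28, a signal of 61.9) were kept, which gave 27022. Gene symbols came from the platform annotation given for the series: of 45037 other probe sets, 34945 had 1 symbol, 932 had several and 9160 were unnamed here, and 34741 of those with 1 symbol matched the reference gene table by gene number. Probe sets with several symbols named no gene. Each gene was represented by its brightest kept probe set, which gave 12859 genes. Of 161 genes measured under the naming rule, 68 had several kept probe sets, and in 19 of these the probe sets differed in sign.

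Differences, 13del-tg minus control, were tested with limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom and 5.01 prior degrees of freedom, and the median standard error was 0.26. Folds are on the log2(signal + 16) scale, which understates changes of dim genes. Lists of marker and pathway genes, 36 in number and fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 where at least 3 members were kept, which held for 35, with Benjamini-Hochberg adjustment over these. At an estimated correlation 0 lists passed, with 2 at an unadjusted p under 0.05. That form of camera rests on the 2 residual degrees of freedom, so small p-values were hardly within reach. The PERK-ATF4-CHOP (estimated correlation -0.030), hypertrophic chondrocyte (-0.22) and collagen modification (-0.029) lists did not pass it either. Failing it is therefore not by itself a sign that the genes of a list move together. fry was run as a further test of the lists: 1 list, that of hypertrophic chondrocytes, passed its directional test and 2, this one and the immediate early list, its mixed test, neither of which compares a list with other genes. The hypertrophic chondrocyte list holds Col10a1 and was not tested without it. The epidermis list had too few kept genes.

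Genes are named by a rule fixed before the data were examined: Col10a1; 12 genes chosen by name for bone remodelling and stress; the 10 largest rises and falls among genes past the threshold whose arrays did not overlap, filled up by the smallest unadjusted p and then said not to pass; up to 4 members with the smallest unadjusted p of each list described; and the sex-linked transcripts. Predicted and Riken genes were replaced by the next gene. Of these, Runx2 and Ddx3y had no kept probe set. Pineal and photoreceptor markers outside this rule were named after their values had been seen.

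The same code was tested on simulated data: 20 sets of 12859 genes in 2 against 2 arrays, with 200 genes changed. With the spread drawn from the fitted prior, 5.52% of genes changed by 1 on the log2 scale were recovered, 65.1% of those changed by 2 and 94.5% of those changed by 4, and 4.32% of calls were false. With each gene's own estimated spread these shares were 33.0%, 90.4% and 99.4%, and 13.2% of calls were false, above the nominal level. Of lists of unchanged, uncorrelated genes 2.43% and 1.86% had a camera p under 0.05. This check does not cover lists whose genes move together. Among lists past the camera threshold, the estimated inter-gene correlation ran from -0.22 (hypertrophic chondrocyte) to 0.98 (skeletal muscle). It was 0.61 for the erythroid list and 0.074 for the endoplasmic reticulum chaperones.

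Alternatives were the pseudocount, quantile normalization or median centring, the filter, each array left out in turn, a replicate block, eBayes without trend or robust, array weights, the mean of a gene's probe sets, leaving out less specific probe sets, a sex-linked covariate, the threshold, the list test and the 3 uses of the shared array. Figures were drawn with matplotlib 3.10.9.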

Results

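Gene expression was measured in the calvaria, the flat bones of the skull roof, of 10-day-old 13del-tg mice and of their wild-type littermates. The 13del-tg line is known from other work to carry a Col10a1 transgene with a deletion that makes a misfolding collagen X chain, and the series' title describes the animals as having bone overgrowth. The labels list 3 biological replicates of each genotype, each on 1 Affymetrix mouse array of 45101 probe sets. The values deposited as control 1 and as 13del-tg 1 were identical for all 45101 probe sets, whereas other pairs of arrays held the same value for 0.115% to 0.213% of them. That array, called the shared array here, carried labels of both genotypes and was left out of the comparison, which set 13del-tg 2 and 3 against controls 2 and 3. Its values are given beside both groups for some genes and lists, without assigning it to either. The deposited intensities of every array had a trimmed mean of 500.003, and the number of arrays, 2 per genotype, limits the precision of each value below.

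The first question was whether the arrays carried the transgene's signal. Col10a1, the collagen of hypertrophic cartilage, gave an intensity of 154 ± 5.94 (SD, n = 2) in the controls and 13637 ± 2902 (SD, n = 2) in 13del-tg. The log2 difference was 6.31 (SE 0.22), about 79.4-fold, with a limma adjusted p of 0.000213. The shared array had a Col10a1 intensity of 152.2, against 149.8 and 158.2 in controls 2 and 3 and 15689 and 11584 in 13del-tg 2 and 3, so its Col10a1 signal lay at the level of the controls, against its 13del-tg label. Only 1 probe set stood for Col10a1, and the labels do not say whether it reads the transgene, the endogenous gene or both. An exact two-sided permutation test gave p = 0.333, the smallest that 2 arrays against 2 allow. The call ended when the shared array was counted as 13del-tg alone (log2 difference 4.20, adjusted p = 0.71) or under both labels (4.21, adjusted p = 1).

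The hypertrophic chondrocyte list, a set of 4 measured genes that includes Col10a1, was higher in 13del-tg by camera (adjusted p = 6.12e-05, median log2 difference 0.40), with adjusted p = 0.504 with an estimated correlation. That form of camera rests on 2 residual degrees of freedom. Its large adjusted p, here and below, does not by itself show genes moving together. Col10a1 was the list's 1 member past the threshold, both over all genes and adjusted over the list alone. The others had smaller differences, Ihh 0.51 (SE 0.38), Panx3 0.29 (SE 0.25) and Mmp13 0.20 (SE 0.23), and the list mean was 1.83. No test without Col10a1 was run, so the list's call cannot be told apart from that of Col10a1. With the shared array as 13del-tg only the list's call ended (median 0.20). The wider chondrocyte list went the other way, with 17 of 18 members negative and a median of -0.83 (camera adjusted p = 0.00223, and adjusted p = 0.755 with an estimated correlation). Against the mean of the controls its median was 0.65 in control 2 and -0.65 in control 3. It was -0.32 in 13del-tg 2, -1.22 in 13del-tg 3 and 0.028 in the shared array, so the groups overlapped. Both 13del-tg arrays lay below both controls for 2 of the list's members. None of its members passed over all genes or adjusted over the list alone by limma, and 1 had an unadjusted p under 0.05. That gene was Epyc, a small cartilage proteoglycan, at -0.90 (SE 0.35), and Cnmd, the cartilage matrix gene of chondromodulin, had -2.23 (SE 0.97), with overlapping groups and values from -3.58 to -0.88 when 1 array was left out. Without 13del-tg 2 the Epyc difference was -0.38. The chondrocyte call was lost without control 2 (median -0.48), without 13del-tg 3 (median -0.32) and with the sex-linked covariate (median -0.32), and without control 3 the median was -1.39.

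**Figure D1:**
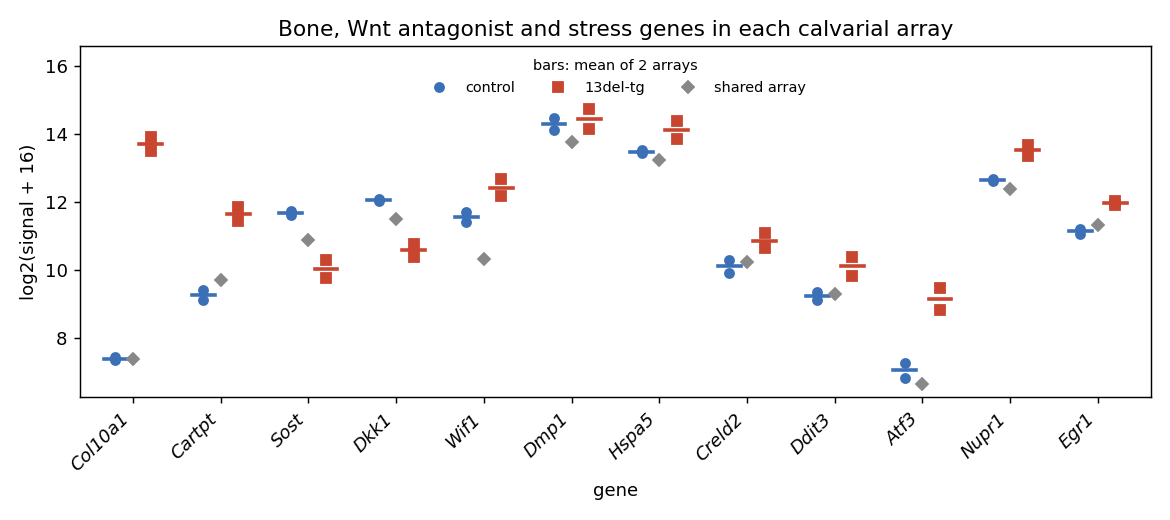
Intensity of 12 genes on each array, as log2(signal + 16), with circles for controls 2 and 3, squares for 13del-tg 2 and 3, diamonds for the shared array and bars for the mean of 2 arrays. Col10a1 lies between 149.8 and 158.2 on the controls and the shared array and at 15689 and 11584 on the 13del-tg arrays, and Sost and Dkk1 lie lower on both 13del-tg arrays than on both controls.

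Across the genome the question was which genes differed between the genotypes. Of 12859 genes tested, 2 were higher and 6 were lower in 13del-tg at an adjusted p under 0.05 by limma. Besides Col10a1, Cartpt, which encodes a neuropeptide precursor, rose 5.15-fold (log2 difference 2.37, SE 0.23, adjusted p = 0.0402), from 613 ± 88.7 to 3244 ± 672 (SD, n = 2 each). The shared array had 832.6, above both controls (550.1 and 675.5) and below both 13del-tg arrays. The next genes in order of unadjusted p did not pass. They were Atf3, a stress-induced transcription factor (2.10, SE 0.33, adjusted p = 0.161), Fst, the activin antagonist follistatin (1.33, SE 0.25, adjusted p = 0.29), Gchfr (1.50, SE 0.28), Sgms1 (1.06, SE 0.20), Esm1 (1.52, SE 0.32), Nupr1 (0.86, SE 0.18), Ptgs2, the inducible prostaglandin synthase (1.72, SE 0.37), and Egr1 (0.84, SE 0.18). The Sgms1 probe sets disagreed in sign. At an unadjusted p under 0.05, 191 genes were higher and 683 lower, the median difference of all genes was -0.074, and both 13del-tg arrays lay on 1 side of both controls for 39.7% of genes, where chance gives 33.3%. Centring each array on its median moved the median of all genes to 0.044 and these counts to 353 and 407. Control 2 and 13del-tg 2 against control 3 and 13del-tg 3 gave 780 genes at an unadjusted limma p under 0.05. The remaining mixed split gave 129 and the genotypes 874, so such a count is not by itself a sign of genotype. Quantile normalization left 1 gene higher, Col10a1, and 1 lower, Chgb, past the threshold, as did a pseudocount of 1 and a 60th percentile filter, and without a filter or without the trend Col10a1 alone passed. Leaving out 1 array, which leaves 1 array in its group, moved the counts past the threshold widely. Cartpt did not pass without 13del-tg 2 or without 13del-tg 3. Its signal was above both controls on each of these arrays, at 2769 and 3719, so the difference stayed. With the shared array counted as a control, Col10a1 was the 1 gene past the threshold (1 higher and 0 lower, with 150 and 648 at an unadjusted p under 0.05), with it as 13del-tg only the counts were 0 and 7 (362 and 534 at an unadjusted p under 0.05), and with it under both labels they were 0 and 0, with 17 genes higher and 175 lower at an unadjusted p under 0.05.

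Chgb, Tph1, Cdhr1, Cplx3, Snap25 and Spink4 were the 6 genes that fell in 13del-tg. Chgb, a granin of dense-core vesicles, fell by 4.37 on the log2 scale (SE 0.32, adjusted p = 0.0175), from 1610 ± 610 to 60.05 ± 2.19 (SD, n = 2 each). Tph1, the serotonin-synthesizing hydroxylase of peripheral tissues and the pineal gland, had a log2 difference of -4.80 (SE 0.43), and Cdhr1, a photoreceptor cadherin, -4.50 (SE 0.46). Cplx3, a complexin of ribbon synapses, had -4.46 (SE 0.45), Snap25, a synaptic fusion protein, -3.86 (SE 0.38), and Spink4, a secreted protease inhibitor, -3.51 (SE 0.36), and all 5 had an adjusted p of 0.0402. The 13del-tg signals of these 6 genes lay at or below the level of the filter, 61.9. The sizes therefore depend on the pseudocount (Snap25 -4.49 with 1 and -2.85 with 64, Chgb -4.67 and -3.71) and are not measured folds. Pde6g (-4.12), Sag (-4.36) and Rbp3 (-2.98), all of photoreceptors, followed with adjusted p from 0.0575 to 0.0658 and did not pass, though all 3 did without control 2, with robust eBayes and with arrays centred on the median. In the shared array Chgb was 68.2, Tph1 51.6 and Snap25 24.2, near the 13del-tg arrays. Of 24 measured markers from a pineal and photoreceptor list written after these genes had been seen, 23 had a negative difference, 16 with an unadjusted p under 0.05, and the median was -2.59. The values of 11 of these had been seen before the list was written, and over the 13 others the median was -0.73, with 12 negative. Markers low on the 13del-tg arrays could pass the filter through their control signals, which favours negative differences. The list of brain genes had a median of -0.043 over 9 members (adjusted p = 0.379), of which Snap25 passed over all genes, and Snap25 and Syt1 (-1.33, SE 0.39) adjusted over the list alone. None of the 6 genes stayed past the threshold with the shared array as a control, when Chgb had a difference of -2.96 (adjusted p = 0.789). With that array as 13del-tg only, Chgb, Cplx3, Snap25, Spink4 and Tph1 stayed and Cdhr1 did not. None of the 6 stayed without 13del-tg 2 or without 13del-tg 3, and Snap25, Cplx3 and Spink4 did not pass without control 3. Each of these fits leaves 1 array in a group. Chgb was alike on 13del-tg 2 and 3, at 61.6 and 58.5, so its difference moved little when either was left out.

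**Figure D2:**
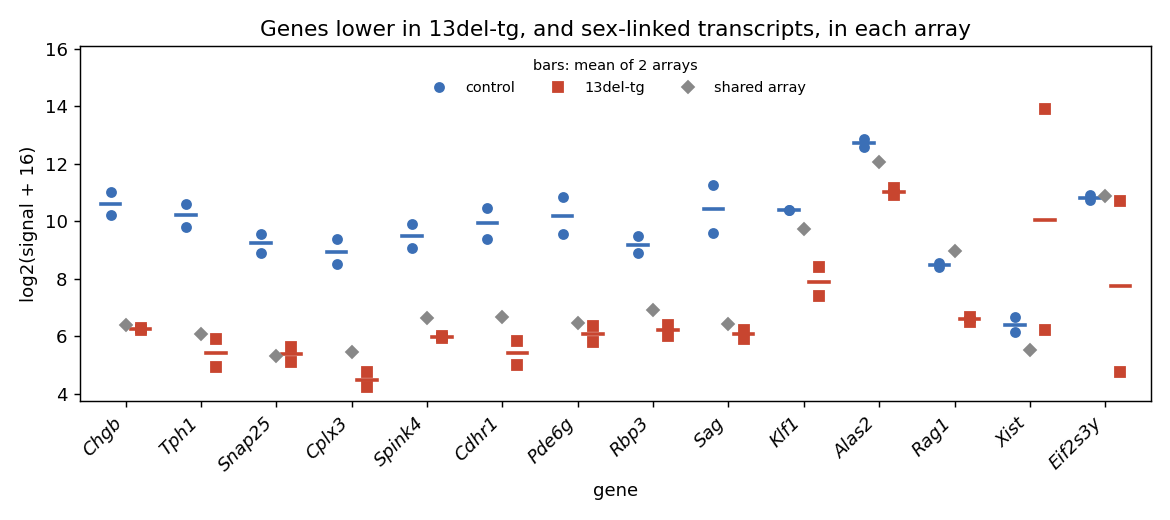
Intensity of 12 genes lower in 13del-tg and of the sex-linked Xist and Eif2s3y on each array, as log2(signal + 16), with symbols for controls 2 and 3 (circles), 13del-tg 2 and 3 (squares) and the shared array (diamonds), and bars for the mean of 2 arrays. Chgb is at 1179 and 2042 on the controls and from 58.5 to 68.2 on the other arrays, the shared array has Rag1 above both controls, and 13del-tg 3 alone has high Xist and low Eif2s3y.

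For bone formation, 2 secreted inhibitors of Wnt signalling made by osteocytes were lower in both 13del-tg arrays without passing over all genes. Sost, which encodes sclerostin, went from 3307 ± 176 to 1062 ± 286 (SD, n = 2 each), a log2 difference of -1.65 (SE 0.24) with an adjusted p of 0.109, and both of its probe sets were negative. Dkk1 went from 4312 ± 132 to 1539 ± 301, a difference of -1.49 (SE 0.21) with an adjusted p of 0.104. Both passed over all genes in 3 of 20 alternatives only: without control 2, with the replicate block and with robust eBayes (adjusted p = 0.0383 each). Both passed adjusted over the list alone in the osteocyte list and in the list of Wnt antagonists, where Wif1 (0.87, SE 0.23), another Wnt inhibitor, passed in the opposite direction. The shared array lay between the groups for Sost, at 1892, and for Dkk1, at 2912, but below both groups for Wif1, at 1268. The Wif1 difference was 0.17 with that array as 13del-tg only and 1.28 with it as control only. Of the 11 Wnt antagonists 9 were negative, with a median of -0.30 (adjusted p = 0.051 by camera, and adjusted p = 0.537 with an estimated correlation), and this list passed without control 3 (median -0.45). The osteocyte list as a whole had a median of -0.027 over 10 genes (adjusted p = 0.658), and Dmp1, an osteocyte matrix protein, had 0.15 (SE 0.25), which turned to -0.039 with quantile normalization. Of 13 Wnt targets, 7 were positive and 6 negative (adjusted p = 0.576), and none passed over all genes or adjusted over the list alone by limma, with 2 higher and 1 lower at an unadjusted p under 0.05. Lgr5, a stem cell receptor, had -1.13 (SE 0.31), the cyclin gene Ccnd1 0.56 (SE 0.22) and the Wnt-inactivating Notum 0.66 (SE 0.26).

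Lists of protein folding and stress genes rose in 13del-tg by small amounts. In the list of endoplasmic reticulum chaperones and degradation factors, 20 of 23 measured genes had a positive difference, with a median of 0.31 (camera adjusted p = 9.66e-08, and adjusted p = 0.504 with an estimated correlation). None of its members passed over all genes or adjusted over the list alone by limma, 4 had an unadjusted p under 0.05, and the median was 0.13 with the shared array as 13del-tg only. Hspa5, the chaperone BiP, had 0.63 (SE 0.22), Creld2 0.75 (SE 0.24), Dnajb9 0.63 (SE 0.21) and Hsp90b1 0.56 (SE 0.19). Xbp1, whose spliced product drives chaperone genes, had 0.41 (SE 0.17). In the list of the PERK, ATF4 and CHOP branch of the stress response, 22 of 26 genes were positive, with a median of 0.27 (adjusted p = 3.48e-07, and adjusted p = 0.504 with an estimated correlation). Atf3 and Nupr1 passed adjusted over the list alone, and none passed over all genes by limma, with 5 at an unadjusted p under 0.05. Psat1, an enzyme of serine synthesis, had 0.65 (SE 0.19), Ddit3, which encodes CHOP, had 0.87 (SE 0.26) with a second probe set of opposite sign, and Atf4 had 0.17 (SE 0.17). Without control 2 the median of this list was 0.15. The immediate early list rose too, with 9 of 11 genes positive, a median of 0.34 and an adjusted p of 0.0017 (adjusted p = 0.586 with an estimated correlation). Egr1 passed adjusted over that list alone, Fosb had 1.25 (SE 0.43) from control signals below the filter's level and 0.77 with a pseudocount of 64, Jun 0.60 (SE 0.22) and Btg2 -0.81 (SE 0.30), and the call was lost without control 2 (adjusted p = 0.0728) or 13del-tg 2 (adjusted p = 0.411).

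The osteoblast list had 9 of 13 genes positive and a median of 0.12 (adjusted p = 0.0306, and adjusted p = 0.586 with an estimated correlation), and the median was -0.0098 with quantile normalization. No member passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 by limma. Ifitm5, a membrane protein of mineralizing osteoblasts, had 0.52 (SE 0.18), the bone sialoprotein gene Ibsp 0.34 (SE 0.17) and the transcription factor gene Sp7 -0.22 (SE 0.26). Collagen modification and export genes had 12 of 16 positive, a median of 0.14 that turned to -0.045 with quantile normalization, and an adjusted p of 0.0306 (adjusted p = 0.504 with an estimated correlation). Again no member passed either adjustment by limma, and 1 had an unadjusted p under 0.05, and among them the prolyl hydroxylase genes P4ha2 and P4ha1 had 0.47 (SE 0.18) and 0.36 (SE 0.18). The calls of these 2 lists were lost without control 2 (medians 0.028 and 0.045), without 13del-tg 3 (0.095 and 0.057), with the sex-linked covariate (0.068 and 0.054) and with the mean of each gene's probe sets (0.11 and 0.062). Osteoblasts lost theirs also without 13del-tg 2 (0.16) and had 0.20 without control 3, and collagen modification had 0.23 without 13del-tg 2. All 15 measured osteoclast genes had a negative difference, with a median of -0.34 (adjusted p = 0.00246, and adjusted p = 0.755 with an estimated correlation). None of them passed over all genes or adjusted over the list alone by limma, and 4 had an unadjusted p under 0.05. On the shared array the medians against the mean of the controls were -0.58 for osteoblast, -0.46 for collagen modification and -0.54 for osteoclast genes. Each lay below the medians of both controls and both 13del-tg arrays. Car2, the carbonic anhydrase of osteoclasts and red cells, had -1.52 (SE 0.43) and -0.78 without 13del-tg 2, Atp6v0d2 -0.63 (SE 0.22) and Mmp9 -0.47 (SE 0.17), whereas the resorption genes Ctsk and Acp5 had -0.0068 (SE 0.17) and -0.19 (SE 0.22), the first turning to 0.11 with arrays centred on the median. The osteoclast call was lost without 13del-tg 2 (median -0.18), without control 3 (-0.28) and with the shared array as control only (-0.19). Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, had 0.92 (SE 0.36, adjusted p = 0.715), with 0.40 without 13del-tg 3 and 1.44 without 13del-tg 2, and its decoy receptor gene Tnfrsf11b had 0.11 (SE 0.41).

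Calvaria hold marrow, and genes of developing blood cells were lower on both 13del-tg arrays. All 9 measured erythroid genes had a negative difference, with a median of -2.21 (camera adjusted p = 2.16e-13, and adjusted p = 0.504 with an estimated correlation), and all 9 passed adjusted over the list alone by limma and had an unadjusted p under 0.05, though none passed over all genes. The erythroid regulator Klf1 had -2.49 (SE 0.35, adjusted p = 0.104), Ermap -2.74 (SE 0.44), Epb42 -2.55 (SE 0.43) and Alas2, the heme synthesis enzyme of red cells, -1.69 (SE 0.20, adjusted p = 0.0658). Epb42 lay below the filter's level on both 13del-tg arrays and had -1.68 with a pseudocount of 64, so its size is not a measured fold. Klf1 and Alas2 each passed over all genes in 3 of 20 alternatives, with robust eBayes among them (adjusted p = 0.0383 and 0.0218). Ermap passed in 2 of 20. In the B cell list all 11 genes were negative, 8 passed adjusted over the list alone, and the median was -1.55 (adjusted p = 4.74e-08, and adjusted p = 0.504 with an estimated correlation) or -0.90 without 13del-tg 2. The recombinase gene Rag1 had -1.89 (SE 0.30), Vpreb3 -1.69 (SE 0.35) and Ms4a1, which encodes CD20, -1.43 (SE 0.28). All 16 proliferation genes were negative, 4 passed adjusted over the list alone, and the median was -0.67 (adjusted p = 5.05e-10, and adjusted p = 0.504 with an estimated correlation). Mki67 had -1.05 (SE 0.21), Aurka -1.16 (SE 0.26), Rrm2 -1.02 (SE 0.23) and Aurkb -0.93 (SE 0.28). Of 3 measured interferon response genes, Rsad2 (-1.94, SE 0.25, adjusted p = 0.0953) and Irf7 (-1.93, SE 0.44) passed adjusted over the list alone, and the list had an adjusted p of 0.000353 (adjusted p = 0.504 with an estimated correlation), lost without a filter on low values (median -0.65, adjusted p = 0.078). Irf7 too lay below the filter's level on both 13del-tg arrays and, with the list's median, moved to -1.25 with a pseudocount of 64. Rsad2 passed over all genes in 3 of 20 alternatives, with robust eBayes among them (adjusted p = 0.0313). The granulocyte list was also lower (median -0.88, adjusted p = 0.00238, and adjusted p = 0.755 with an estimated correlation), but its median was -1.59 in 13del-tg 2 and 0.13 in 13del-tg 3, each against the mean of the controls. Ltf, a granule protein gene, had -1.05 (SE 0.44), and the granulocyte call was lost without 13del-tg 2 (0.13), without control 3 (-0.51) and with the shared array as 13del-tg only (-0.48), with -1.59 without 13del-tg 3.

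Skeletal muscle genes were higher in 13del-tg as a list, with 14 of 15 positive and a median of 1.70 (adjusted p = 2.32e-09, and adjusted p = 0.586 with an estimated correlation). The 2 controls stood apart on this list, control 2 at 1.54 and control 3 at -1.54 against their mean. The shared array lay at 2.07, 13del-tg 2 at 2.19 and 13del-tg 3 at 1.49, so control 3 alone was low. In both splits of the 4 arrays that mixed the genotypes the muscle and granulocyte lists passed as well. The osteoclast and chondrocyte lists passed in 1 of these splits and the proliferation list in the other. The muscle median was 0.27 without control 3, 3.28 without control 2 and 1.07 with the shared array as control only. Myh8, the perinatal myosin heavy chain, had 2.31 (SE 0.95) and Pvalb 2.12 (SE 0.82), and no member passed over all genes or adjusted over the list alone by limma, with 2 at an unadjusted p under 0.05. Most of the muscle difference came from control 3, and the sex-linked transcripts set 13del-tg 3 apart. Both arrays entered the main comparison of all the gene groups above. Xist, the transcript of the inactive X chromosome, had an intensity of 15206 in 13del-tg 3 and from 29.9 to 84.5 on the other distinct arrays, and the Y-linked Eif2s3y had 11.1 in 13del-tg 3 and from 1652 to 1910 on the others. With the sex-linked score as a covariate, Col10a1 was the 1 gene past the threshold (1 higher and 0 lower, with 161 and 604 at an unadjusted p under 0.05). That fit has 1 residual degree of freedom. In it the differences of the 6 lower genes ran from -5.29 (Tph1) to -3.58 (Spink4). Chgb had -4.37 (SE 0.41, adjusted p = 0.137) and Cartpt 2.16 (SE 0.23), so the lost calls do not show an effect of sex. The score was -8.43 in 13del-tg 3 and from 2.16 to 3.24 on the other arrays fitted. The fit therefore mostly sets 13del-tg 2 against the controls and cannot separate sex from that 1 female-like array. The 3' to 5' ratio of the Gapdh control probe sets was 0.737 to 0.866 and that of beta-actin 1.06 to 1.40 over the 5 distinct arrays. Their log2 intensities correlated across probe sets with Pearson's r from 0.910 to 0.967, probe sets not being independent replicates.

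**Figure D3:**
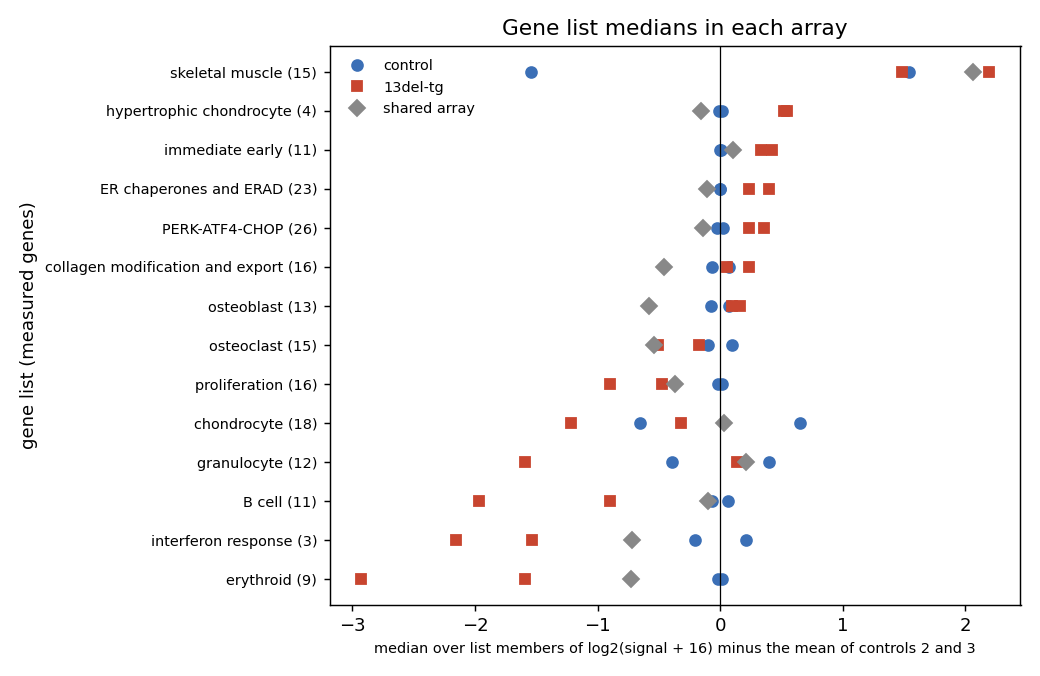
Median over the measured genes of each of the 14 lists past the camera threshold, per array, as log2(signal + 16) minus the mean of controls 2 and 3, with circles for controls, squares for 13del-tg and diamonds for the shared array. The erythroid median is -2.93 in 13del-tg 2, -1.59 in 13del-tg 3 and -0.73 in the shared array, and the muscle medians of the controls lie at 1.54 and -1.54.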

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

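This comparison was chosen after the values had been seen. The poly-A spike-in probe sets, which read bacterial transcripts added to the RNA before labelling and enter no comparison of the report, stood out in 13del-tg 3 because their signal exceeded that of the controls. Their median log2 excess over the higher control was 0.96, with a median intensity of 2806 against 1082 in control 2, 1706 in control 3, 984 in 13del-tg 2 and 1100 in the shared array. All 12 of these probe sets had their highest value in 13del-tg 3. The hybridization spike-ins, added later, were 0.20 above the higher control on that array.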

How the results depend on the processing

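The 3 settings that bring the shared array back and the counts over other splits were chosen after the data were seen. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the other group. Col10a1 passed in 18 of 20 alternatives, with differences from 4.20 to 6.53, and ended with the shared array under both labels (4.21) or as 13del-tg only (4.20), where that array lies at the control level. Genes higher and lower were 1 and 1 with pseudocount 1, with quantile normalization and with the 60th percentile filter, 1 and 2 with pseudocount 64, 1 and 0 without a filter (unadjusted p under 0.05: 265 and 930), without trend (149 and 781), with the sex-linked covariate (161 and 604) and with the shared array as control only (150 and 648), 0 and 0 with it under both labels (17 and 175), and 0 higher and 7 lower with it as 13del-tg only (362 and 534). Robust eBayes gave 23 lower and an adjusted p under 0.1 gave 17 lower. Leaving out 1 array gave 1 to 182 higher and 0 to 50 lower. The same replicate numbers across groups share no stated litter or batch. Over genes, the deviations of control 2 and 13del-tg 2 from their group means correlated at 0.27. With 2 arrays per group, replicate 3 gives the same value by construction. With a replicate block, which leaves 1 residual degree of freedom, the counts were 271 and 338. In that fit the osteoblast (median 0.12) and collagen modification (0.14) lists did not pass, and the Wnt antagonist (-0.30) and megakaryocyte (-0.97) lists passed. The 3 splits of the 4 arrays are too few for a share under 0.05: 1 split, the real one, gave 8 or more genes, and the highest of the others gave 1, and 1 split, the real one, gave 14 or more lists, and the highest of the others gave 7. Genes at an unadjusted p under 0.05 numbered 874 in the real split, 780 with control 2 and 13del-tg 2 against the others and 129 with control 2 and 13del-tg 3, and of the 14 lists osteoclast, chondrocyte, muscle and granulocyte passed in the first of these and muscle, granulocyte and proliferation in the second. Lists past the threshold numbered 0 with an estimated correlation, 1 with fry's directional test and 2 with its mixed test; the medians are then those of the report (erythroid -2.21, B cell -1.55, proliferation -0.67, interferon -1.93, chondrocyte -0.83, granulocyte -0.88, osteoclast -0.34, muscle 1.70, chaperones 0.31, PERK branch 0.27, hypertrophic 0.40, immediate early 0.34, collagen modification 0.14, osteoblast 0.12). Erythroid, B cell, proliferation, chaperone, PERK branch and muscle lists passed in 20 of 21 camera alternatives each, the estimated correlation being the exception. None of them passed fry, with directional adjusted p from 0.105 (PERK branch) to 0.742 (muscle) and mixed adjusted p from 0.12 to 0.61. Under other settings some of the 14 lists did not pass and some of the 21 others did, with these medians: with quantile normalization, osteoblast -0.0098, collagen modification -0.045, Wnt antagonists -0.26 and megakaryocyte -0.90; with arrays centred on the median, Wnt antagonists -0.18 and megakaryocyte -0.85; without a filter, osteoblast 0.12 and interferon -0.65; with the 60th percentile filter, collagen modification 0.14; with the mean of probe sets, osteoblast 0.11, collagen modification 0.062, tRNA synthetases 0.15 and Wnt antagonists -0.37; with the sex-linked covariate, osteoblast 0.068, collagen modification 0.054, chondrocyte -0.32, tRNA synthetases 0.21, suture fibroblasts 0.13 and megakaryocyte -1.73; with the shared array under both labels, osteoblast 0.080 and collagen modification 0.092; as control only, osteoclast -0.19, tRNA synthetases 0.26, BMP targets 0.14 and suture fibroblasts 0.24; and as 13del-tg only, osteoblast -0.11 (reversed), hypertrophic 0.20, collagen modification -0.054, granulocyte -0.48 and megakaryocyte -0.81. Leaving out 1 array, medians ran from 0.028 to 0.20 for osteoblast, -1.39 to -0.32 for chondrocyte, 0.045 to 0.23 for collagen modification, -0.072 to 0.24 for hypoxia and glycolysis, 0.33 to 0.44 for immediate early, -0.51 to -0.18 for osteoclast, -0.45 to -0.18 for Wnt antagonists, 0.057 to 0.13 for suture fibroblasts, -0.38 to -0.075 for adipocyte, -1.59 to 0.13 for granulocyte, 0.032 to 0.20 for tRNA synthetases and -1.78 to -0.087 for megakaryocyte. Among named genes that did not pass in the report, leaving out 1 array moved several by over 1.5 times, among them Cnmd (-3.58 to -0.88), Car2 (-2.26 to -0.78), Tnfsf11 (0.40 to 1.44), Epyc (-1.42 to -0.38), Hspa5 (0.36 to 0.91), Atp6v0d2 (-0.89 to -0.37), Btg2 (-1.20 to -0.41), Ltf (-1.61 to -0.50), Notum (0.43 to 0.90), Myh8 (0.61 to 4.01), Pvalb (0.67 to 3.57), Ppbp (-2.56 to -0.19), Gp9 (-2.93 to -0.056), Vwf (-1.40 to -0.55) and Eif2s3y (-6.06 to -0.12). Sost, Dkk1, Klf1, Alas2 and Rsad2 passed over all genes without control 2, with robust eBayes and with the replicate block, Atf3, Ermap, Myh8 and Pvalb without control 2 and with the block, and Epb42, Irf7, Ppbp, Gp9 and Vwf with the block alone. Further named genes passed in 1 of 20 alternatives, among them Car2, Cnmd, Rag1, Mki67, Hspa5 and Tnfsf11. The named genes that changed sign did not pass in the report: Dmp1 (-0.039 with quantile normalization, -0.14 with the sex-linked covariate, -0.077 with the shared array as 13del-tg only, -0.15 to 0.45 leaving out 1 array), Ctsk (0.11 centred on the median, 0.23 with the shared array as control only, -0.13 to 0.11), Acp5 (0.0020 with it as control only, -0.41 to 0.024), Sp7 (0.11 with the covariate, 0.050 with the shared array as control only, -0.57 to 0.13), Tnfrsf11b (-0.026 with it as 13del-tg only, -0.32 to 0.54), Atf4 (-0.00057 with it as 13del-tg only) and Xist (-0.20 to 7.49, high on 13del-tg 3 alone). Of all single-gene values under the alternatives 1361 kept direction and side, 73 lost the call, 83 gained one and 19 changed sign, and of list tests, with the direction taken from camera, these numbers were 664, 44, 22 and 2. Apart from the fewer arrays or genes in some settings, the cause was not tested. For the 6 genes that fell and for Epb42, Irf7, Sag, Nkg7 and Neurod1, 13del-tg levels were at or below the filter's signal of 61.9. Their folds therefore depend on the pseudocount.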

Other observations

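The tests on the 3 patterns weighed in the later paragraphs were chosen after the results they bear on had been seen. The lists that did not pass the camera threshold also held named genes that stood apart. The megakaryocyte list had 4 of 4 genes negative and a median of -0.97 (adjusted p = 0.0672), made up of -1.78 in 13del-tg 2 and -0.087 in 13del-tg 3 against the mean of the controls. Ppbp, a platelet chemokine, had a log2 difference of -1.38 (SE 0.66) and Gp9, a platelet adhesion receptor, -1.49 (SE 0.83), with -0.19 and -0.056 without 13del-tg 2. Of 14 endothelial genes 11 were negative (median -0.19, adjusted p = 0.576), and Vwf, the von Willebrand factor gene of endothelium and platelets, had -0.98 (SE 0.34) and -0.55 without 13del-tg 3. Among 4 T and NK cell genes the cytotoxic granule gene Nkg7 had -1.20 (SE 0.38), with a list median of -0.16 (adjusted p = 0.658). Macrophage genes had a median of -0.073 over 11 members (adjusted p = 0.862), and no gene of these lists passed over all genes or adjusted over the list alone by limma, with Vwf and Nkg7 alone at an unadjusted p under 0.05. Ptgs2 passed adjusted over the list of inflammatory cytokines alone, a list with a median of -0.40 and a mean of 0.032 (adjusted p = 0.658). Median, mean and the direction of camera did not all share a sign in 7 lists, those of Wnt targets, inflammatory cytokines, meninges, osteoclast regulators, mineralisation, the hedgehog pathway and macrophages. Over the 21 lists that did not pass, adjusted p ran from 0.051 to 0.96.

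The pineal gland lies under the skull roof. Of the 6 genes that fell, Snap25 is on the brain list, and Chgb, Tph1 and Cdhr1 are on the pineal and photoreceptor list. Neurod1 is another (-4.15, not past the threshold and chosen after its value was seen). Its 13del-tg signals, 50.2 and 8.3, lay below the filter's level, so its size is not a measured fold. Pineal tissue in the 2 control samples is therefore a candidate explanation that sections of parietal bone would not rule out. Brain tissue as the source of these falls was set against the brain list. Its median was -0.043 (SD over genes 1.36, SE 0.57) against -4.41 for the 6 genes. Its median signal was 8.5 higher in the controls (SD 342) against 840 for the 6. The 6 genes were chosen by their falls and share Snap25 with the list, so this contrast in size cannot decide the question. Of the 9 list members 4 were positive and 5 negative, so brain genes did not fall as a list. Of the 39 markers written for the pineal test, 11 had been seen beforehand and none is in a fixed list. Of the 24 measured, 9 lay above the filter's level on both 13del-tg arrays. The 13 unseen and measured markers had a median of -0.73, with 12 negative and at percentile 0.02 of 10000 random lists matched on expression. The median falls between the bounds of -1 and -0.5 set for this test. Markers low on the 13del-tg arrays could pass the filter through their control signals. This median and percentile therefore rest partly on that selection. Unseen markers above the filter's level on both 13del-tg arrays were Scg3 (-0.87), Aanat (-0.73), Unc119 (-0.52), Gngt1 (-0.26), Rom1 (-0.15), Gngt2 (-0.12) and Drd4 (0.44). Aanat, a melatonin enzyme, had 167 and 248 in the controls and 107 and 126 in 13del-tg, and Crx 97.7 and 208 against 61.6 and 55.1. Otx2 and Tulp1, also unseen, differed more. Otx2 had 338 and 510 against 43.8 and 1.5, and Tulp1 361 and 845 against 58.1 and 84.3. Drd4 was the unseen marker with a positive difference (0.44). Of the 24 markers 22 were higher in control 3 than in control 2. The genotype could not be told apart from pineal tissue, since the shared array had a median 2.62 below the controls on these markers (-2.62) and its own genotype is open. Its Col10a1 signal, 152.2, lay at the level of the controls. Low values of these markers were therefore not confined to arrays with a high Col10a1 signal, though 1 array does not settle the question.

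Erythroid, B cell and proliferation genes were lower on both 13del-tg arrays, and 3 technical or sampling explanations were set against a difference between genotypes. One smaller share of marrow for all lineages stayed open: the erythroid median lay 1.53 below the granulocyte median (-1.53, mean of 13del-tg 2 and 3), with -1.33 and -1.72 on the 2 arrays against a gap of 0.76 between the controls, but it lay at -0.94 on the shared array, which, counted as a control, would widen that gap to 1.32. Dilution by skeletal muscle was tested in the controls, where control 2 exceeded control 3 by 3.09 on muscle genes and its erythroid median differed by -0.032 (SE over genes 0.13). The sex of 13del-tg 3 does not account for the fall in 13del-tg 2, whose Xist and Eif2s3y were like the controls' and which had the lower erythroid median, -2.93 (SE over genes 0.23). A difference in the make-up of the marrow with genotype, or between the sampled pieces of bone, may remain, and with the shared array as control only the erythroid median was -1.94.

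The array deposited as control 1 and as 13del-tg 1 could be a control, a 13del-tg pup with little Col10a1 signal, or a file deposited under wrong names. Its Col10a1 lay 6.11 on the log2 scale below the lower of 13del-tg 2 and 3 (-6.11), which differ by 0.44, so a 13del-tg array with the transgene signal of those 2 is argued against. Across probe sets it correlated at 0.961 with control 2, 0.960 with 13del-tg 2, 0.942 with 13del-tg 3 and 0.910 with control 3. This order does not follow genotype, but neither did the correlations among the other arrays. Control 2 had 0.967 with 13del-tg 2 and 0.946 with control 3, so these correlations cannot tell the array's genotype. Which label is right stays open, and the array was assigned to neither group.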
